A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

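Expression was measured in *S. cerevisiae* BY4741 and a trk1 trk2 double mutant on 4 dual-colour arrays, each carrying mutant and wild-type cDNA in opposite dyes. Per the labels, 50 ml cultures were grown at 28 °C and collected by filtration, and 8 µg of total RNA was copied from an oligo(dT) primer and labelled with Cy3 or Cy5 by an indirect dUTP method. The labels describe 2 independent experiments, each hybridised again with the dyes exchanged, but do not say which arrays belong together. The array titles number each array as an experiment of its own, which neither pairs them nor matches that description. Arrays 1 and 2 were taken as experiment 1 and arrays 3 and 4 as experiment 2, because each pair shares the wording of its description field and holds both dye orientations. The other dye-balanced pairing, arrays 1 and 3 with 2 and 4, was an alternative. Only the descriptions' word independent says that the experiments came from separate cultures.

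The values used are the deposited log2 ratios of each array, as the authors processed them. Per the labels, the authors did not consider spots under 120 µm in diameter or under 100 fluorescence units, and such cells are empty. The scanner, the normalization, the centring and the base of the logarithm are not given in the sources used here. Base 2 was assumed, so every fold change rests on that reading. The array titles name mutant against wild type, with the dyes in that order, but the labels do not state the direction of the deposited ratio. The columns correlate positively although the dyes were exchanged, so they had been turned to one direction, and the negative values of TRK1 and TRK2 show that direction to be mutant over wild type. The array medians were −0.02, −0.09, −0.10 and 0.01 and their SDs 0.56, 0.53, 0.57 and 0.65. Scanner intensities were not used here, so spot brightness could not be used to weigh a value, and the number of arrays sets the precision.

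The table has 6212 rows, of which 4255 had a value on 4 arrays, 503 on 3, 463 on 2, 407 on 1 and 584 on none. Row names were matched to locus tags of a RefSeq gene table, 5644 exactly and 18 ignoring case, and 550 rows were left without a symbol and named in no list. The table was used for symbols and neighbouring genes only, and no coordinates are printed. Probe sequences were not used here, so signal shared between near-identical genes could not be separated.

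The main test averaged the arrays of an experiment and compared the 2 experiment means with 0, in genes with a value on all 4 arrays, using limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 5.34 degrees of freedom. Data were simulated with 4255 genes drawn independently of each other, 200 of them changed. The procedure recovered 7.91% of genes changed 1.5-fold, 63.6% of those changed 2-fold and 98.9% of those changed 4-fold. It made 10.2 false calls in a simulation on average, a larger share of its calls than the threshold of 0.05 allows. A count without a test took genes at least 1.5-fold changed in the mean with the same sign on all 4 arrays.

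The named genes were TRK1, TRK2 and the auxotrophic markers, the 12 highest and 12 lowest mean ratios among genes past an adjusted p of 0.05 with the same sign on all 4 arrays, and every potassium list member past the test. For each list past camera, the 4 members with the largest mean change in the list's direction and the same sign on all 4 arrays were added. Other genes named in the text, such as the remaining called list members, MDH2, PHO5, PMA1 and the lysine genes, were chosen after their values were seen. A total of 29 gene lists and this rule were chosen before the data were examined, except that RPP1 (YHR062C), an RNase P subunit that a name pattern had put among the ribosomal proteins, was taken out after its values were seen. The lists cover potassium and sodium transport, phosphate, sulfur, iron, zinc and nitrogen regulons, amino acid synthesis, stress and wall pathways, carbon metabolism, ribosomes, mating, histones, sterols, the proteasome and the vacuolar proton pump. Of these, 25 had at least 3 genes on all 4 arrays and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The alpha-specific list had 1 gene on all 4 arrays and the marker list 2, the subtelomeric Y' helicases had 0, and the mitochondrially encoded genes had 0 rows, so these were not tested. The result of 1 tested list and its members is not reported here, although the counts of lists and genes include it. Camera called 2.6% of unchanged simulated lists at an unadjusted p under 0.05 and 0% after adjustment. The simulated genes were independent, so these rates do not cover lists whose genes vary together. The stress list, for example, had an estimated correlation of 0.866 on the 4 arrays.

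Alternatives changed the pairing, used the 4 arrays as separate replicates with or without a dye term or with the experiment as a random block, centred or scaled the arrays, changed the filter on empty cells, the shrinkage, the thresholds or the test, and left out each array or experiment in turn. Camera with correlations estimated on the 4 arrays was added after seeing the data, since 2 experiment means estimate them poorly. With an estimated correlation camera also takes its degrees of freedom from the few arrays, which leaves it little power. Dye was fitted as a term on the 4 unaveraged arrays. The arrays of an experiment are dye-swapped repeats, so fits of 4 separate arrays count them as independent replicates. The consensus correlation of the random block was −0.046, so that fit did not guard against this either. Genes sharing the most frequent ratio of an array, within 0.003 and on at least 3 arrays, were counted after seeing the data. Of 14 such genes none passed the test, and on array 2 the most frequent ratio, −0.17, was a different one from that shared by the glycolysis genes.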

Results

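The transcript profile of a *Saccharomyces cerevisiae* strain without TRK1 and TRK2, the genes of the high-affinity potassium uptake system, was set against that of the wild type BY4741. The comparison asks which transcripts differ when this system is missing while potassium is plentiful. Cells grew in a medium whose own potassium was 15 µM, supplemented with 50 mM KCl, and were harvested in log phase at an A600 of 0.6. Mutant and wild-type cDNA were hybridised together on 4 dual-colour arrays, from 2 independent experiments with a dye swap in each. The mutant carried Cy5 on arrays 1 and 4 and Cy3 on arrays 2 and 3. The arrays gave 4797, 4690, 4972 and 5403 values among 6212 listed rows, and 4255 genes had a value on all 4. The number of arrays limits the precision. Each value is a log2 ratio of mutant over wild type, averaged over the arrays of an experiment and then over the experiments. Errors are limma's moderated standard errors with n = 2 experiments, and adjusted p-values are limma's after Benjamini-Hochberg adjustment.

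The deleted genes gave strongly negative ratios wherever they were listed. TRK1 (YJL129C) stood at −6.13 on array 1 and −4.60 on array 4, a mean of −5.36 ± 1.08 (SD, n = 2 arrays). The gene is deleted in the mutant, so the ratio sets a limit and not a level, and no fold is given. TRK1 was empty on arrays 2 and 3, and its adjusted p was 0.00796 in a limma fit of genes with a value on at least 1 array of each experiment. TRK2 (YKR050W) was listed on array 4 alone, at −4.23, with no replicate and the same limit. Both genes therefore read lower in the mutant on arrays where it carried Cy5. The orientation of arrays 2 and 3 rests on their positive correlation with the others. Among the auxotrophic markers of the strain, HIS3 (YOR202W) rose 2.18-fold (log2 ratio 1.13 ± 0.16, adjusted p = 0.0228), although without array 3 its adjusted p was 0.395. URA3 (YEL021W) read −0.56 ± 0.24 (adjusted p = 0.262, and 0.0257 with the other pairing), and LEU2 and MET17 were empty on all 4 arrays. Auxotrophic markers are genes that do not function in the strain, so these ratios may not be changes in expression of an intact gene.

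The gene that fell most among those on all 4 arrays was PHO84 (YML123C), the high-affinity phosphate transporter, with a 40.7-fold lower ratio in the mutant (log2 ratio −5.35 ± 0.34, adjusted p = 0.00274). HSP12 (YFL014W), a stress-induced membrane protein, fell 19.9-fold (−4.32 ± 0.47, adjusted p = 0.00836), and SIT1 (YEL065W), a siderophore transporter, 12.1-fold (−3.60 ± 0.20, adjusted p = 0.00274). PHO84 (−6.71 on array 2) and HSP12 (−6.76 on array 4) read lower than the deleted TRK1 did on either of its arrays. Scanner intensities were not used, so background in the mutant channel could not be told from expression. The folds of PHO84 and HSP12 may therefore be limits and not levels. The highest ratios belonged to CIT2 (YCR005C), the peroxisomal citrate synthase, at 8.24-fold (3.04 ± 0.31, adjusted p = 0.00642), and DLD3 (YEL071W), a D-2-hydroxyglutarate dehydrogenase, at 6.89-fold (2.78 ± 0.21, adjusted p = 0.00298). Of 4255 genes tested, 69 rose and 74 fell past an adjusted p of 0.05, and 138 of these 143 had the same sign on all 4 arrays. All 143 changed by more than 1.5-fold, the smallest by 0.86 on the log2 scale. The labels leave the pairing of arrays open, and with the other dye-balanced pairing 255 genes passed as higher and 473 as lower. That pairing leaves the means unchanged but takes its error from the interaction of dye and experiment. The SD of this contrast over genes was 0.166, against 0.232 for the difference between experiments. If arrays 1 and 2 do form an experiment, that difference drops out of the error. The added calls therefore hold only if the other pairing is the right one. The calls also depended on the arrays used: 93 genes passed without array 1, 62 without array 2, 0 without array 3 and 217 without array 4. With 1 array left out, the remaining array of its experiment stood alone, without a dye swap. Without array 3, experiment 2 was array 4 alone, which correlated least with the others. Losses of calls without array 3 therefore do not single out array 3 as their source. Every call was lost there, so such a loss, where it is given below, does not set a gene apart from the other called genes. Without array 3 the smallest adjusted p in limma was 0.193, with 385 genes at an unadjusted p under 0.05. All 143 called genes kept their sign there, which for 138 of them follows from having the same sign on all 4 arrays. CIT2, HSP12 and SIT1 stood at 3.84, −3.64 and −4.20 without array 4, and at 2.24, −4.99 and −3.0 without array 3.

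**Figure D1:**
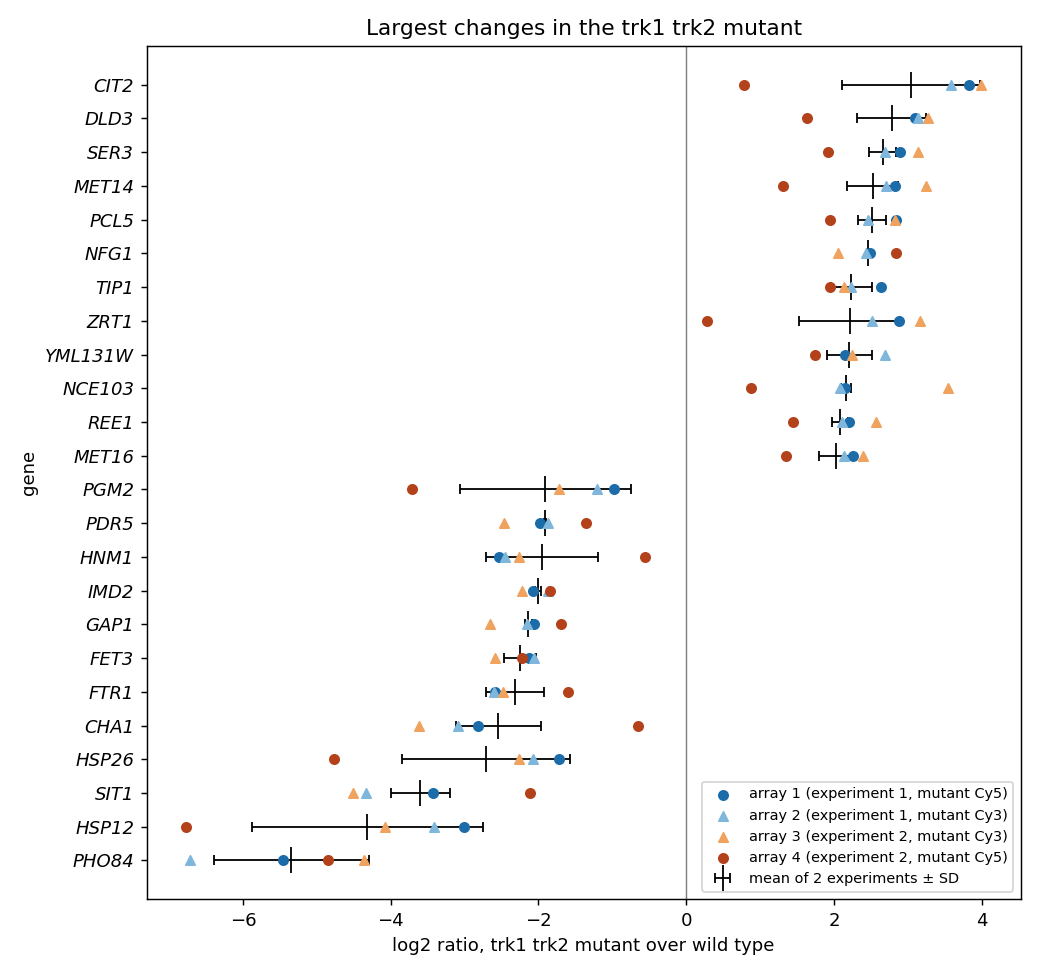
Log2 ratio of mutant over wild type for the 12 genes with the highest and the 12 with the lowest mean ratios, with a point for each array and the mean of 2 experiments ± SD as a black bar. All 4 points of each gene lie on one side of 0, by the rule that chose these genes. The means run from −5.35 for PHO84 to 3.04 for CIT2, and array 4 lies apart for CIT2, ZRT1, HSP12 and HNM1.

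Also among the 12 highest, SER3 (YER081W), which catalyses the first step of serine synthesis, rose 6.31-fold (2.66 ± 0.17), and PCL5 (YHR071W), a cyclin that targets Gcn4 for degradation, rose 5.72-fold (2.52 ± 0.17), each with an adjusted p of 0.00274. NFG1 (YLR042C), a cell wall protein, rose 5.48-fold (2.45 ± 0.16, adjusted p = 0.00274) and TIP1 (YBR067C), a cell wall mannoprotein, 4.71-fold (2.24 ± 0.18, adjusted p = 0.0033). ZRT1 (YGL255W), the high-affinity zinc transporter, rose 4.63-fold (2.21 ± 0.25, adjusted p = 0.0102), and NCE103 (YNL036W), the carbonic anhydrase, 4.47-fold (2.16 ± 0.16, adjusted p = 0.00298). YML131W, a putative oxidoreductase, rose 4.61-fold (2.20 ± 0.18, adjusted p = 0.00354) and REE1 (YJL217W), a cytoplasmic protein, 4.23-fold (2.08 ± 0.17, adjusted p = 0.00327). Without array 3 none of these calls held, with adjusted p from 0.195 for NFG1 to 0.563 for ZRT1, and ZRT1 also missed the threshold with 4 separate arrays and a dye term (adjusted p = 0.0564). Array 4 lowered some means: without it ZRT1 stood at 2.93 and NCE103 at 2.83, and without array 3 both stood at 1.49.

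Also among the 12 lowest, CHA1 (YCL064C), the catabolic serine and threonine deaminase, fell 5.84-fold (−2.55 ± 0.23, adjusted p = 0.00423), and GAP1 (YKR039W), the general amino acid permease, 4.40-fold (−2.14 ± 0.16, adjusted p = 0.00298). IMD2 (YHR216W), an IMP dehydrogenase, fell 4.01-fold (−2.0 ± 0.16, adjusted p = 0.0033), and its value is uncertain because near-identical copies can hybridise to the same spot. HNM1 (YGL077C), the choline transporter, fell 3.87-fold (−1.95 ± 0.27, adjusted p = 0.0205) and PDR5 (YOR153W), a multidrug efflux pump, 3.78-fold (−1.92 ± 0.16, adjusted p = 0.00354). CHA1 stood at −3.29 without array 4 and at −1.81 without array 3. Without array 3 these calls ended, with adjusted p from 0.252 for IMD2 to 0.520 for CHA1 and HNM1.

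In the potassium and sodium transport list, 1 of 13 measured members passed over all genes tested and 2 when adjusted over the list alone, and 11 of the 13 had a negative mean. QDR2 (YIL121W), a drug transporter linked to potassium uptake, fell 3.14-fold (−1.65 ± 0.16, adjusted p = 0.00587). NHX1 (YDR456W), an endosomal cation/proton exchanger, read −0.69 ± 0.16 (adjusted p = 0.0834) and passed with the experiment as a random block (adjusted p = 0.0226), with 4 separate arrays and with the other pairing. Here and below, the random block and the 4 separate arrays in effect count dye-swapped repeats as replicates. Calls gained with the other pairing hold only if that pairing is the right one. The kinase PTK2 and the phosphatase PPZ1, regulators of ion transport, read −0.35 and −0.32. TOK1, the outward potassium channel, stood at −0.20 and PMA1, the plasma membrane proton pump, at −0.41, neither past the test (adjusted p = 0.513 and 0.423). PMA1 read −1.085, −0.746, 0.081 and 0.114 on arrays 1 to 4. Its value on array 4 is the most frequent ratio of that array, so an absence of change cannot be read from it. The sodium pump ENA1 and the antiporter NHA1 were empty on all 4 arrays. The list was lower in camera, a test against the other genes (median −0.29, adjusted p = 0.0352), and did not pass with correlations estimated on the 4 arrays (adjusted p = 0.463 with an estimated correlation). Its camera adjusted p was 0.229 without array 4 and 0.194 over genes with at least 2 values on unaveraged arrays, and QDR2's adjusted p was 0.267 without array 3. The filter of at least 2 values brought the deleted TRK1 itself into the list, as did that of at least 1 array of each experiment.

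Camera placed the phosphate list (median −0.27, adjusted p = 0.00474) and the iron list (median −0.21, adjusted p = 0.0024) lower, but for both the adjusted p = 0.5 with an estimated correlation. In the phosphate regulon, PHO84, VTC3 and VTC1 fell, 3 of 17 measured members over all genes, and when adjusted over the list alone 6 fell and 1, PHO5, rose. VTC3 (YPL019C) and VTC1 (YER072W), subunits of the vacuolar polyphosphate synthase, fell 3.51-fold (−1.81 ± 0.21, adjusted p = 0.0116) and 1.92-fold (−0.94 ± 0.18, adjusted p = 0.0473), while the subunit VTC2 read −0.70 (adjusted p = 0.1, and 0.0267 with a random block). PHO5, an acid phosphatase, read 0.63 ± 0.18 and did not pass over all genes (adjusted p = 0.117, and 0.035 with the other pairing). In the iron regulon 3 of 17 members fell, and 4 when adjusted over the list alone. These were SIT1 and both parts of the high-affinity iron uptake system, FTR1 (YER145C; 4.99-fold, −2.32 ± 0.20, adjusted p = 0.00354) and FET3 (YMR058W; 4.77-fold, −2.25 ± 0.17, adjusted p = 0.00298). The vacuolar oxidase FET5 read −0.79 (adjusted p = 0.0606) and passed with the other pairing (adjusted p = 0.0109), with 4 separate arrays (0.0131) and in 5 more alternatives. Of the 17 iron genes 15 had a negative mean, but the list mean, −0.65, lay well below the list median. Other members moved little, among them FIT1 (−0.002), ARN1 (−0.19) and FRE1 (0.12). The call of VTC1 ended when any 1 array was left out, with a log2 ratio between −0.86 and −1.03, and with scaled arrays (adjusted p = 0.0808). SIT1 stood at −4.20 without array 4 and −3.0 without array 3, and without array 3 adjusted p ran from 0.193 for PHO84 to 0.395 for VTC1.

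The sulfur and methionine genes were higher as a list, with a median of 0.65 (camera adjusted p = 9.69e-10, adjusted p = 0.463 with an estimated correlation). The list median was positive on every array but smallest on array 4, at 0.88, 0.88, 0.60 and 0.37 on arrays 1 to 4. Of 22 measured members 8 rose and 0 fell, and 13 rose when adjusted over the list alone. They included MET14 (YKL001C) and MET16 (YPR167C), which activate and reduce sulfate, at 5.74-fold (2.52 ± 0.19, adjusted p = 0.00298) and 4.09-fold (2.03 ± 0.17, adjusted p = 0.00366). MET10 (YFR030W) and MET5 (YJR137C), the sulfite reductase subunits, rose 3.54-fold (1.82 ± 0.17, adjusted p = 0.00479) and 3.46-fold (1.79 ± 0.17, adjusted p = 0.00443). The remaining called members were MET1, MET3, MET28 and the sulfate permease SUL2. The methionine synthase MET6 read 0.39 (adjusted p = 0.261). Without array 3 the adjusted p of these members ran from 0.272 for MET10 to 0.622 for MET28, and the call of MET28 also ended without array 1 or 2 and with a dye term (adjusted p = 0.0911).

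Amino acid biosynthesis genes controlled by Gcn4 were higher as a list (41 measured, median 0.12, camera adjusted p = 0.000271, adjusted p = 0.5 with an estimated correlation). Over all genes 5 rose and 0 fell, and 16 passed when adjusted over the list alone, 15 of them higher. Besides SER3, these were CPA1 (YOR303W), a carbamoyl phosphate synthase subunit, at 2.76-fold (1.46 ± 0.19, adjusted p = 0.0179), HIS5 (YIL116W) at 2.09-fold (1.07 ± 0.17, adjusted p = 0.035), ARO4 at 2.0-fold (adjusted p = 0.0369) and HOM3 at 1.92-fold (adjusted p = 0.0434). The mitochondrial ornithine transporter ORT1 read 1.07 ± 0.21 (adjusted p = 0.0512) and passed in 7 alternatives, among them the random block (adjusted p = 0.0191) and the fit without array 4 (0.0229). The 7 measured lysine genes stood apart on array 4, where their median was −2.60 against 0.28, 0.13 and 0.84 on arrays 1, 2 and 3, and the other 34 members had a median of 0.31 there. Without array 3 the list's adjusted p was 0.0746 and no member passed, with adjusted p from 0.253 for SER3 to 0.548 for CPA1 and HIS5. HIS5, ARO4 and HOM3 also lost their calls without array 1 or array 2, CPA1 with 4 separate arrays and a dye term, and HIS5 and HOM3 with scaled arrays (adjusted p = 0.0537 and 0.0631).

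General stress genes controlled by Msn2 and Msn4 were lower as a list (33 measured, median −0.37, camera adjusted p = 0.00277, adjusted p = 0.744 with an estimated correlation). Over all genes 7 fell and 2 rose, and when adjusted over the list alone 8 fell and 2 rose. HSP12 led, followed by the small heat shock protein HSP26 (YBR072W; 6.53-fold, −2.71 ± 0.36, adjusted p = 0.0179), the phosphoglucomutase PGM2 (YMR105C; 3.75-fold, −1.91 ± 0.36, adjusted p = 0.0483) and the glutamate decarboxylase GAD1 (YMR250W; 3.65-fold, −1.87 ± 0.30, adjusted p = 0.0347). The remaining called members that fell were MSC1, TFS1 and GSY1, at −1.59, −1.86 and −1.71. GSY1 read 0.004 on array 1 and lost its call with the other pairing (adjusted p = 0.0669). MSC1 and TFS1 lost theirs with a dye term (adjusted p = 0.0689 and 0.0516). The 2 that rose were DDR48 at 1.94-fold (adjusted p = 0.0472) and YGP1, a cell wall protein, at 2.16-fold (adjusted p = 0.0401). The shift of the list was carried by array 4, with a median of −1.33 there against 0.12, 0.01 and −0.32 on arrays 1, 2 and 3. Without array 4 the list's median was −0.11 and its adjusted p 0.423, while HSP12 still fell by 3.64 on the log2 scale (adjusted p = 0.00354) and HSP26 by 2.08 (adjusted p = 0.00554). Without array 3 HSP12 stood at −4.99 (adjusted p = 0.298) and HSP26 at −3.33 (adjusted p = 0.406), and PGM2, GAD1, DDR48 and YGP1 lost their calls without array 1, 2 or 3. HSP12 missed the threshold with robust shrinkage (adjusted p = 0.0521), PGM2 and DDR48 with a dye term (0.0749 and 0.056), and GAD1 and YGP1 with scaled arrays (0.0587 and 0.0662).

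Mating genes were higher as a list in camera (median 0.76, adjusted p = 9.69e-10), but not with correlations estimated on the 4 arrays (adjusted p = 0.138 with an estimated correlation). The list median was positive on every array. Of 18 measured members of the a-cell and pheromone response list 7 rose and 0 fell, 12 rose when adjusted over the list alone, and 15 were positive on all 4 arrays. AGA1 (YNR044W) and AGA2 (YGL032C), the subunits of a-agglutinin, rose 3.15-fold (1.66 ± 0.21, adjusted p = 0.0169) and 2.90-fold (1.53 ± 0.16, adjusted p = 0.00799). PRM6 (YML047C), a pheromone-regulated protein that takes part in potassium transport, rose 3.77-fold (1.92 ± 0.36, adjusted p = 0.0473) and ASG7 (YJL170C), an a-specific protein, 3.76-fold (1.91 ± 0.29, adjusted p = 0.0262). FUS1, KAR4 and the a-factor gene MFA2 also rose, by 2.20-fold, 2.22-fold and 1.89-fold. SAG1, encoding alpha-agglutinin and the only gene of the alpha-specific list with a value on all 4 arrays, rose 1.98-fold (0.98 ± 0.16, adjusted p = 0.036). The alpha-factor gene MF(ALPHA)1 and the a-factor receptor gene STE3 of that list were listed on array 4 alone, at 3.54 and 0.92. Without array 3 these genes lost their calls, with adjusted p from 0.272 for AGA2 to 0.521 for ASG7. PRM6, MFA2 and SAG1 did so without array 1 or 2, and ASG7 and FUS1 without array 2. PRM6 and ASG7 also missed the threshold with a dye term (adjusted p = 0.0614 and 0.0558), and FUS1, MFA2 and SAG1 with scaled arrays (0.0544, 0.0609 and 0.0507).

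**Figure D2:**
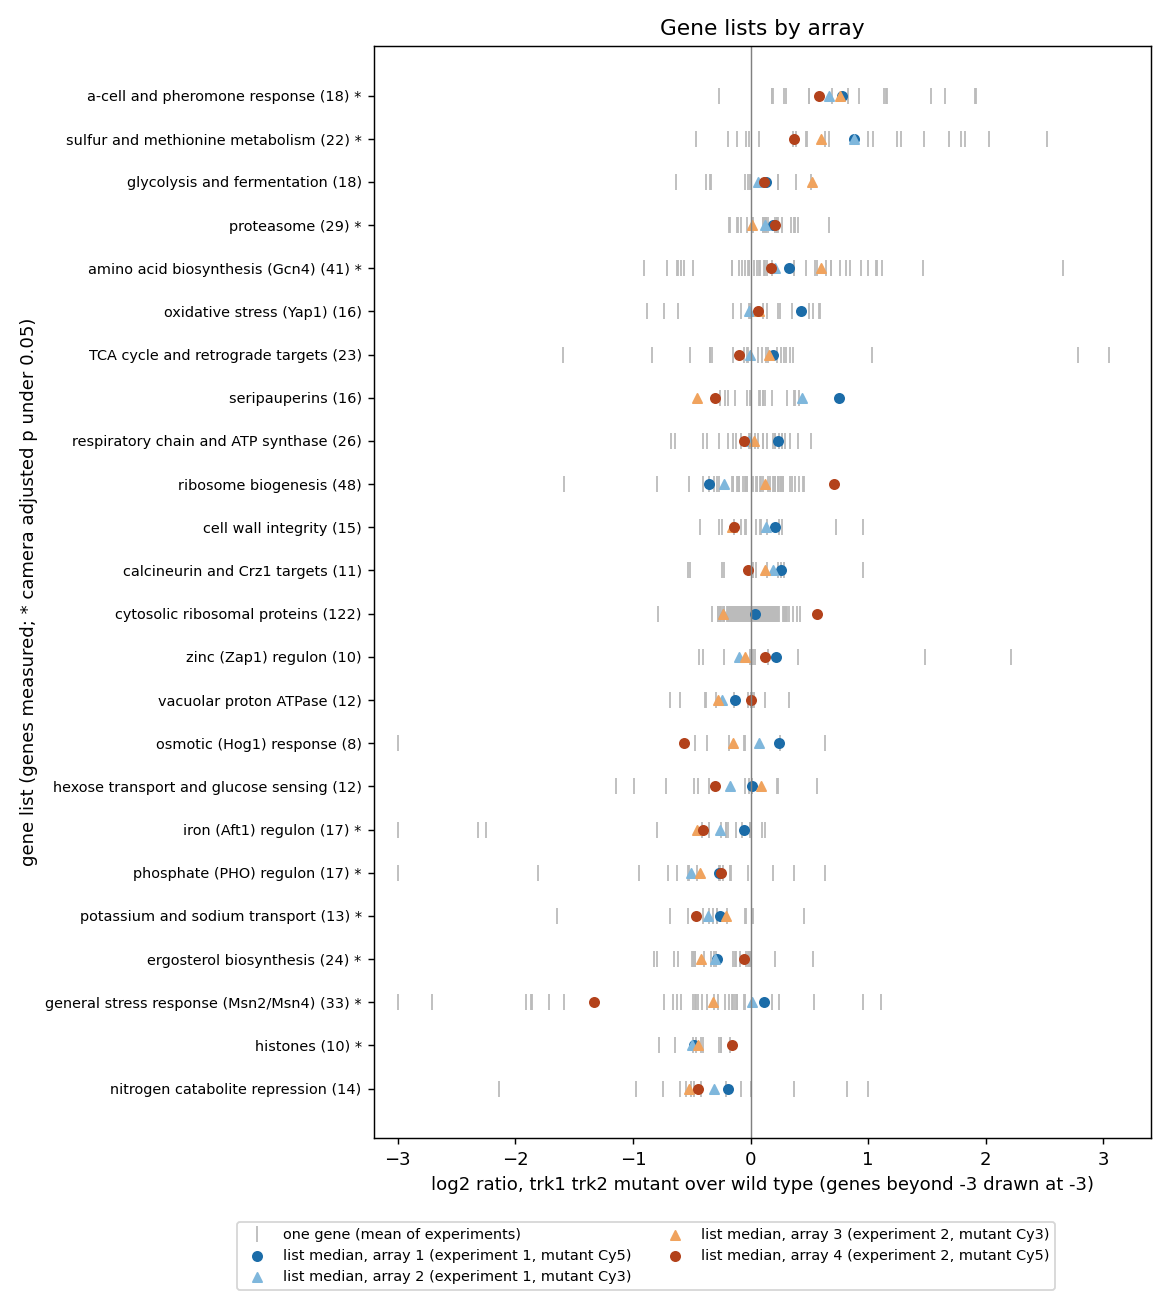
Gene lists by array, with each list's median log2 ratio of mutant over wild type on each array as a coloured point and each measured gene's mean of 2 experiments as a grey tick; genes below −3 are drawn at −3, and a star marks a camera adjusted p under 0.05. The mating list lies between 0.58 and 0.78 on the 4 arrays, whereas the general stress list lies at −1.33 on array 4 and between −0.32 and 0.12 on the others.

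Histone, ergosterol and proteasome genes shifted as lists in camera without any member past the main test over all genes. All 10 histone genes had negative means, 9 of them negative on all 4 arrays, and 2 passed when adjusted over the list alone (median −0.41, camera adjusted p = 0.0024, adjusted p = 0.547 with an estimated correlation). HTA2 and HTB2, an adjacent pair encoding H2A and H2B, read −0.78 ± 0.17 (adjusted p = 0.0639) and −0.64 ± 0.17 (adjusted p = 0.1), the linker histone HHO1 −0.49 and the H4 gene HHF1 −0.46, and the core histone pairs are near-identical copies that the spots may not separate. Of 24 ergosterol genes 21 were negative and 3 passed when adjusted over the list alone (median −0.31, camera adjusted p = 0.0112, adjusted p = 0.635 with an estimated correlation). ERG25 read −0.82, ERG7 −0.79, ERG4 −0.65 and the HMG-CoA reductase HMG1 −0.62. The ergosterol list median was −0.28, −0.30, −0.42 and −0.06 on arrays 1 to 4, so the shift was nearly absent on array 4. Of 29 proteasome genes 23 were positive, with PUP3 at 0.67, PUP2 at 0.41, RPN12 at 0.38 and RPN9 at 0.36, and 0 passed when adjusted over the list alone (median 0.13, camera adjusted p = 0.0168, adjusted p = 0.5 with an estimated correlation). With the other pairing the 4 histone and 4 ergosterol genes named here and PUP3 passed, with adjusted p from 0.0108 for ERG7 to 0.0436 for HHF1, and all of these but HMG1 also passed with a random block (adjusted p = 0.0195 for HTA2 and 0.0251 for PUP3). The ergosterol list's camera adjusted p was 0.115 without array 3, and that of the proteasome list was 0.0648 without array 4.

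Of the 25 lists tested, 5 were higher and 6 lower in camera with its preset correlation of 0.01. None passed when correlations were estimated on 2 experiments (0 lists at an unadjusted p under 0.05, smallest adjusted p = 0.797), when they were estimated on the 4 arrays (2 lists, smallest adjusted p = 0.138) or in fry, a rotation test of each list on its own (5 lists, smallest adjusted p = 0.241). With an estimated correlation camera also takes its degrees of freedom from the few arrays, so a list could hardly pass whatever its correlation. The mating list's estimate on the 4 arrays, −0.023, lay below the preset 0.01, yet its camera p went from 5.4e-11 to 0.00553. These failures therefore do not show that correlation between genes explains the list shifts. The 14 other lists did not pass camera, although several held called members. GAP1 fell and the arginase CAR1 rose (1.99-fold, adjusted p = 0.0369) in the nitrogen catabolite repression list, where 5 of 14 fell and 2 rose when adjusted over the list alone (median −0.45, camera adjusted p = 0.0809). In the TCA cycle and retrograde list CIT2, DLD3 and the pyruvate carboxylase PYC1 (2.04-fold, adjusted p = 0.0312) rose and the malate dehydrogenase MDH2 fell 3.02-fold (adjusted p = 0.00642), and 3 of 23 rose and 2 fell when adjusted over the list alone (median 0.10, camera adjusted p = 0.271). ZRT1 and ADH4 (2.79-fold, adjusted p = 0.0472) rose in the zinc list, with 2 of 10 adjusted over the list alone (median 0.03, camera adjusted p = 0.281), and HXT3 fell 1.99-fold (adjusted p = 0.0436) in the hexose transport list, with 2 of 12 (median −0.20, camera adjusted p = 0.284). ADH4 read 0.73 without array 4 and 2.22 without array 3, and lost its call when any 1 array was left out, as did HXT3 (adjusted p = 0.0975 without array 4). ADH4 also lost it with a dye term (adjusted p = 0.0991), HXT3 with scaled arrays (0.0736), and CAR1 and PYC1 over genes with at least 1 array of each experiment (0.0675 and 0.0596). Without array 3, MDH2, CAR1 and PYC1 also lost theirs (adjusted p = 0.267, 0.395 and 0.589), CAR1 did so without array 1 or 2 and PYC1 without array 2, and the nitrogen list passed without array 1 (camera adjusted p = 0.0493) at the preset correlation. On all 4 arrays it had an adjusted p = 0.547 with an estimated correlation.

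The cell wall integrity list and the calcineurin list share the glucan synthase GSC2, which rose 1.94-fold (adjusted p = 0.0407). It was the only member of either past the test, with 2 of 15 and 1 of 11 when adjusted over the list alone (medians 0.05 and 0.05, camera adjusted p = 0.352 and 0.522). SOD1, the copper and zinc superoxide dismutase, fell 1.84-fold (adjusted p = 0.0473) in the oxidative stress list, with 3 of 16 lower and 3 higher when adjusted over the list alone (median 0.12, camera adjusted p = 0.289). The osmotic list, which shares HSP12 with the general stress list, had 1 of 8 past over all genes, and 1 lower and 1 higher when adjusted over the list alone (median −0.12, camera adjusted p = 0.449). Ribosome biogenesis genes had 1 of 48 past the test both over all genes and adjusted over the list alone, the RNA helicase DBP2, which fell 3.0-fold (adjusted p = 0.0412; list median 0.05, camera adjusted p = 0.34). No member passed, over all genes or adjusted over the list alone, among 122 ribosomal proteins (median 0.04, camera adjusted p = 0.204), 26 respiratory genes (0.08, 0.361), 16 seripauperins (0.09, 0.34, with medians of 0.61 in experiment 1 and −0.39 in experiment 2) and 12 vacuolar proton ATPase genes (−0.08, 0.289). No glycolysis gene passed either (18 measured, median 0.24, camera adjusted p = 0.204), but for many of them the ratio is a shared value, so an absence of change cannot be read from it. On arrays 1, 3 and 4, 9 of its genes, among them TDH3, ENO2, PDC1 and CDC19, lay within 0.003 of 0.128, 0.639 and 0.114, the most frequent ratio of each array. The other 9 glycolysis genes had a median of −0.05. The ribosomal proteins had medians of 0.03, −0.24, −0.24 and 0.56 on arrays 1 to 4, and the list passed camera at the preset correlation as higher without array 2 (adjusted p = 0.00769) or array 3 (adjusted p = 1.64e-05). On all 4 arrays its estimated correlation was 0.805 and its adjusted p = 0.853 with that correlation, and its median was −0.16 without array 4 and −0.03 without array 1. The ribosome biogenesis median was −0.05 without array 4. Without array 3 adjusted p was 0.491 for SOD1 and 0.523 for GSC2 and DBP2, and these 3 genes also lost their calls without array 1 or 2 and with scaled arrays (adjusted p = 0.0755, 0.0553 and 0.0783).

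A size rule gave a broader count: 165 genes were at least 1.5-fold higher and 284 at least 1.5-fold lower in the mean with the same sign on all 4 arrays, 10.6% of the genes tested. The same rule found 8 genes for the dye contrast of the 4 arrays, 50 for the difference between experiments and 4 for their interaction. In a limma fit of the 4 arrays with a dye term, 0 genes passed for dye, 195 had an unadjusted p under 0.05, and the dye effect had an SD of 0.20 over genes. The arrays were not equally close. Across 4255 genes, which are not independent replicates, Pearson's r was 0.796 for arrays 1 and 2 and 0.392 for arrays 3 and 4. It was 0.688 for arrays 2 and 3, 0.552 for arrays 1 and 3, and 0.304 and 0.273 for array 4 with arrays 1 and 2.

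**Figure D3:**
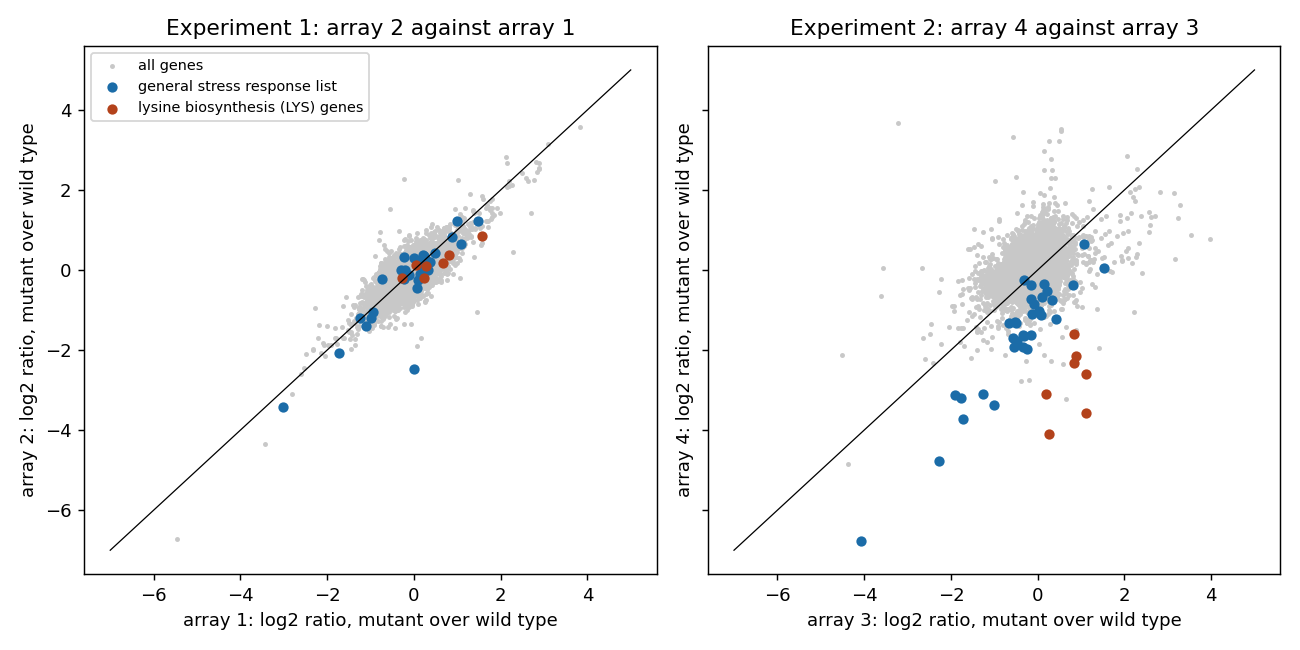
Log2 ratio of mutant over wild type on the dye-swapped array of each experiment, array 2 against array 1 and array 4 against array 3, with a grey point per gene measured on 4 arrays, the general stress list in blue, the lysine genes in red and the line of equality in black. The lysine genes lie between −0.28 and 1.57 on arrays 1 to 3 and between −4.10 and −1.60 on array 4.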

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

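The tests of random spot noise, for which genes sharing a common ratio were left out, and of a different culture or RNA on array 4, and the comparison of the lysine genes, were chosen after the result was seen. Of 89 values compared over the 4 arrays, 7 had an array far from the other 3, and chance sets about 1 in 20 such groups apart. Array 4 was the one apart in 6 of them. CIT2 read 0.78 on array 4 against 3.58 to 3.99 elsewhere, and DLD3 1.63 against 3.09 to 3.28. FTR1 read −1.60 against −2.60 to −2.48, HNM1 −0.56 against −2.53 to −2.27 and HMG1 −0.08 against −0.85 to −0.77. The histone list median was −0.16 on array 4 against −0.50 to −0.45. The glycolysis list median was 0.53 on array 3 against 0.06 to 0.13 on the others, but 9 of the 18 genes shared the array's most frequent ratio (0.639 on array 3), so this departure is that of a common value and not of separate genes. The 9 other glycolysis genes had a median of 0.05 on array 3. Over all 4255 genes 288 were set apart in this way, 6.77%, and 164 of them by array 4 against 39, 27 and 58 by arrays 1, 2 and 3.

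Between arrays 3 and 4, 10 of 25 lists differed by more than random lists of their size, which argues against random spot noise. Array 4 minus array 3 had a median of 0.84 for ribosomal proteins and −1.22 for general stress genes. The 7 lysine genes, singled out because of their values on array 4, had −3.31, which describes the pattern and tests nothing. A dye effect would also appear between arrays 1 and 2, which have the same dye contrast, but the differences correlated at r = 0.221 across genes (bootstrap range 0.177 to 0.265), which argues against dye as the main cause. A different culture or RNA on array 4 may lie behind it and stays open: arrays 3 and 4 correlated at 0.392 against 0.796 for arrays 1 and 2, the labels do not say which arrays share RNA, and a processing difference and a strain difference in that culture were not separated.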

How the results depend on the processing

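Camera with correlations estimated on the 4 arrays was chosen after seeing the data. No list past camera changed direction under any alternative run, while 7 lists that had not passed changed the sign of their median in at least 1. No named called gene changed direction, but all had the same sign on all 4 arrays, most by the rule that chose them. That all but fixed the outcome for these genes. Of the 143 called genes, 142 also passed with the other pairing, 135 with 4 separate arrays, 121 with a dye term, 138 with a random block, 143 centred, 81 scaled, 73 with at least 1 array of each experiment, 128 with at least 2 values, 133 with robust shrinkage, and 90, 61, 0 and 133 without arrays 1, 2, 3 and 4. Counts of higher and lower genes were 69 and 74 in the main test, 255 and 473 with the other pairing, 163 and 250 with 4 separate arrays, 103 and 142 with a dye term added, and 185 and 292 with the experiment as a random block. They were 123 and 131 with median-centred arrays, 44 and 37 (more higher than lower) with arrays also scaled, 40 and 39 with at least 1 array of each experiment, 130 and 179 with at least 2 values, and 128 and 177 at an adjusted p of 0.1. An unmoderated test over 4 arrays gave 445 and 534 at an unadjusted p under 0.05 and 0 and 0 after adjustment (smallest adjusted p in that test 0.0661). Leaving out each array gave 0 to 96 higher and 0 to 121 lower (36 and 26 without array 2), and for the 1.5-fold rule 169 to 204 higher and 259 to 402 lower. That rule gave 275 and 381 without experiment 1, 254 and 434 without experiment 2, 55 and 62 at 2-fold, and 331 and 543 at 1.3-fold, as looser or stricter thresholds must. The ratio of TRK2 was −3.97 on scaled arrays, by construction. The number of lists past camera was 11, 8 to 12 without single arrays, 10 with at least 2 values, and 0 with correlations estimated on 2 experiments, with those estimated on 4 arrays and with fry. Each named gene that lost its call on scaled arrays also lost it with at least 1 array of each experiment, as did ARO4, CAR1 and PYC1. Elsewhere the cause was not tested. Of the other values, 750 for genes and 316 for lists were counted as unchanged, 71 and 6 became weaker and 79 and 3 stronger. Unchanged means the same side of the threshold, except for the means of genes without experiment 1 or experiment 2. Those means had no test and counted among the 750 by construction. Of 38 named called genes, PGM2, PRM6 and VTC1 lost their calls most often, in 8, 7 and 6 of 13 alternatives. Each ratio already pairs both strains on 1 array, and the experiment as a random block is among the fits above. With a consensus correlation of −0.046 the block was close to 4 separate arrays, so its added calls rest on repeats counted as replicates. The added calls of the other pairing rest on its smaller error, which is valid only if that pairing is right. Depth is set by the number of arrays, since signal over background was not used here.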

Other observations

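The tests of phospholipid, drug efflux, purine and copper genes and of the chromosomes and neighbouring genes were planned only after the changed genes were seen, and each list was tested on the members not first noticed among them. The members left come from the same arrays and some were themselves called, so camera on them is no independent check. Phospholipid synthesis genes under Ino2 and Ino4 were tested as a group. INO1, the inositol-3-phosphate synthase, fell 3.54-fold (adjusted p = 0.00423), the fatty acid synthase FAS1 2.60-fold (adjusted p = 0.0473), and HNM1 3.87-fold. Of the 10 members not first noticed, OPI3, a phospholipid methyltransferase, fell 2.20-fold (adjusted p = 0.0228) and the regulator OPI1 1.85-fold (adjusted p = 0.0473), while CHO2, CPT1 and CKI1 read −0.81, −0.77 and −0.66 without passing in the main test, and passed with the other pairing (adjusted p = 0.0344, 0.0258 and 0.0171). Only these 2 passed in the main test. The median of the 10 was −0.64, and camera gave p = 2.1e-06, but p = 0.161 with an estimated correlation. Lower expression of this regulon as a whole may be part of the mutant profile, a hypothesis that needs other samples. INO1 read 0.05 on array 4 against −3.57 to −1.75 on the others, and stood at −2.73 without array 4 and −0.92 without array 3. Without array 3 no gene of this list passed (adjusted p from 0.492 for OPI3 to 0.622 for INO1 and OPI1). INO1 and OPI1 also missed the threshold with 4 separate arrays (adjusted p = 0.0631 and 0.0574) and FAS1 with a dye term (0.0516).

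Drug efflux genes under Pdr1 and Pdr3 included PDR5, the oligomycin pump YOR1 (3.14-fold lower, adjusted p = 0.0142), AQR1 (2.95-fold lower, adjusted p = 0.0142) and QDR2. Of the 8 members not first noticed, SNQ2, TPO1 and TPO4 fell, by 1.90-fold, 2.04-fold and 2.20-fold, and the others did not pass. AQR1 read 0.06 on array 4, and stood at −2.24 without array 4 and −0.88 without array 3. Without array 3 none of these genes passed (adjusted p from 0.267 for QDR2 to 0.622 for AQR1), and AQR1 missed the threshold with a dye term (0.063) and SNQ2, TPO1 and TPO4 with scaled arrays (0.0735, 0.0537 and 0.0519). Camera gave p = 0.0506 (median −0.23, p = 0.275 with an estimated correlation), just short of the threshold, which leaves a group-wide shift open. Purine and GTP synthesis genes without IMD2 and IMD3 had a median of −0.30 over 17 genes, and camera gave p = 0.00963 (p = 0.281 with an estimated correlation), with 0 members past the test in limma. A small joint shift may be present there. The metallothionein copies CUP1-1 and CUP1-2, which one spot cannot separate, rose 3.74-fold and 3.91-fold (adjusted p = 0.00799 and 0.00423), and did not pass without array 3 (0.253 and 0.252). The 5 other measured copper genes had a median of −0.27 and ran from −0.88 for SOD1, which fell, to 0.34. The upper end of the confidence interval of their mean (t-based, over genes) was 0.307 against 1.90 for CUP1-1, a comparison chosen after the result was seen. It argues against a rise of these 5 genes together by about as much as CUP1. It takes the genes as replicates, and whether they are regulated with CUP1 was not tested, so it says nothing of a copper response in other genes. A small shift of the group stays open (camera adjusted p = 0.27 over 5 genes).

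No chromosome stood apart: the largest departure of a chromosome's median from that of all genes was −0.053, which argues against an extra chromosome in the mutant. Of the 4 genes beside TRK1 and TRK2, 2 changed by at least 1.5-fold in the mean. These were URA2, with a mean of −0.85 (adjusted p = 0.154, and 0.00892 with the other pairing; −1.46, −1.35, −0.32 and −0.27 on arrays 1 to 4), and HFL1, with a mean of −0.96 on 3 arrays. PBS2 read −0.10 and FMP46 0.35. A local effect of the deletions on their neighbours could be neither shown nor excluded with 4 genes.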
